A study of Mus musculus with 4 samples.

How the data were processed

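The samples were 4 libraries of mouse T-helper 2 primary cells, all in 1 group, with replicate numbers 1 to 4 taken from the labels, which call them biological replicates and give each its own biosample. The labels call the assay total RNA-seq, while the library protocol they link to is named for poly(A) RNA. The values used are the authors' deposited fragment counts per gene, raw and not normalized. Per the file headers, the counts were made with featureCounts v1.4.6-p4 on coordinate-sorted STAR alignments, with paired fragments counted over exons, both ends required to map, the strand option set to 1, annotation GENCODE M13 and assembly mm10. The STAR version is not given in the sources used here. The header names call the alignment stranded and the sample a 72 h sort, and the replicate number in 4 of 4 headers matched the label. A second text in each deposit lists files and was not used.

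Gene symbols and biotypes were taken from GENCODE M21 by gene identifier without its version. Of 50600 identifiers, 50376 matched, and 50367 of these lay on the same chromosome and strand with overlapping bounds. The 224 unnamed identifiers held 0.402% to 0.477% of the counts and stayed in all tests. Coordinates are those of the count files. TPM was computed from the deposited counts and the exon length in the files, and CPM from the total count. The design fixed earlier had assumed deposited TPM and expected counts with posterior means and credibility intervals. The files hold counts, so TPM was computed from them, and the alternatives that need posterior means or credibility intervals were not run.

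Exons of each gene were set against exons of genes on the other strand with bedtools 2.31.1, and any shared sequence of at least 1 bp counted as an opposite exon. Of the 50600 genes, 42411 had none. Shares of counts have Wilson intervals at 95%. A feature was called nested where at least 80% of its length lay in exons of 1 longer protein-coding gene on the other strand and the pair had at least 20 counts.

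Log2 ratios of TPM + 1 between fixed gene pairs, and differences between the median log2(TPM + 1) of fixed gene lists, were taken within each library and tested over the 4 libraries with an exact two-sided sign-flip permutation test, whose smallest p is 0.125. The 27 gene lists covered T-helper fates (Th2, Th1, Th17, regulatory, follicular helper), naive, activated and inhibitory states, cytokines, T cell identity, other cell types (CD8 and natural killer, B, myeloid, granulocyte, red cell and platelet, stromal), proliferation, glycolysis, interferon, stress, cholesterol, histones with and without poly(A), structured noncoding RNAs, mitochondrial mRNAs and rRNAs, and sex-linked genes. Pairs, lists, tests of pairs and lists and the rule for named genes were set before the data were examined. List medians were placed among 10000 random lists of detected genes, and each library's mean log2 deviation among 10000 random lists matched on mean expression.

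Spread between replicates was measured over genes with a mean count of at least 10 by a chi-square test against Poisson sampling with TMM-scaled library sizes, by the common dispersion of edgeR 4.0.16, and by edgeR's quasi-likelihood test of each library against the other 3, with Benjamini-Hochberg adjustment at 0.05. DESeq2 1.42.0 was the alternative. R 4.3.3 and Python 3.11.15 were used. Because the labels name biological replicates, the spread includes differences between cultures or animals as well as technical ones. Median-of-ratios factors differed from TMM by at most 0.07 on the log2 scale.

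The tests were tried on simulated counts drawn from the real means and library sizes of 7752 genes. With Poisson counts and no change, the chi-square test called 0 genes. With 200 genes raised in replicate 1, it recovered 96.5% at 2-fold and 100% at 4-fold. At the observed dispersion, the edgeR test of 1 library against 3 recovered 0% of 200 genes at 2-fold, 1.5% at 4-fold and 85.5% at 16-fold, so it reaches only very large differences.

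Named genes were those of the fixed pairs and panel, the 4 highest members of each list and the 2 lowest of each fate list, the 10 genes of highest TPM, the 10 of widest spread among genes with a mean TPM of at least 10, and per library the 3 highest and 3 lowest called genes with a mean TPM of at least 5. Genes named only as the partner of another on the opposite strand, or among the highest counts, were chosen after their values were seen. Alternatives were another pseudocount (0.1), FPKM, list members with a mean TPM of at least 1, a TPM of at least 5 for detection, TPM rescaled over nuclear genes without histones and structured RNAs, other size factors, no filter on low counts, and leaving out each library. Restrictions to genes with or without an opposite exon were added after the data were seen. Some results of this rule and of the fixed pairs are not reported here.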

Results

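Gene-level RNA-seq counts were analysed for 4 biological replicates of mouse T-helper 2 (Th2) cells, the CD4 T cell type that makes the cytokines IL-4, IL-5 and IL-13. The cells were primary cells of strain C57BL/6NJ, and the file headers place them at 72 h, after a sort. All 4 libraries belong to 1 group, so the comparisons are between genes within a library and between the replicates. The total gene count was 1780682 in replicate 1, 1857433 in replicate 2, 1446040 in replicate 3 and 1274431 in replicate 4. At this depth 3 counts correspond to 1.62 to 2.35 counts per 1000000 (CPM), the limit that a count of 0 allows. Intervals and this limit cover counting error only. A TPM of at least 1 in all 4 libraries was reached by 6318 genes.

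Nearly all of the genes with the most counts had an exon opposite an exon of another gene on the other strand. Gm20721, annotated within the exons of Gnas on the opposite strand (chromosome 2, 174330319 to 174346712, mm10), had 21429 ± 1586 CPM (SD, n = 4). Phykpl, which shares 809 bp of exon with Hnrnpab on the other strand, had 13989 ± 971 CPM, and Tlcd1, opposite the ribosomal protein gene Rpl23a, had 13131 ± 1712 CPM. CT010467.1, an rRNA entry opposite Gm42418 on chromosome 17, took 2.87% (95% Wilson interval 2.84 to 2.90) of the counts of replicate 4 and 5.73% (5.69 to 5.76) of those of replicate 2. Of the 100 genes with the highest mean count, 98 had an exon opposite an exon of another gene. Such genes made up 16.2% of the annotation, yet held 83.6% (83.5 to 83.6), 91.5% (91.4 to 91.5), 90.9% (90.8 to 90.9) and 79.9% (79.8 to 79.9) of the counts of replicates 1 to 4. The annotation includes genes without a count. Of the 7752 genes with a mean count of at least 10, 3925 had an opposite exon. In the mitochondrial genome mt-Nd6, the only mRNA gene of its strand, had 38990 to 49626 counts per kb, while the 12 mRNA genes of the other strand had at most 2853 in any library. The 79 ribosomal protein genes together held 0.673% to 1.95% of the counts. A TPM below is therefore a measure of the counts on the annotated strand of a gene and was not taken as its mRNA level.

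**Figure D1:**
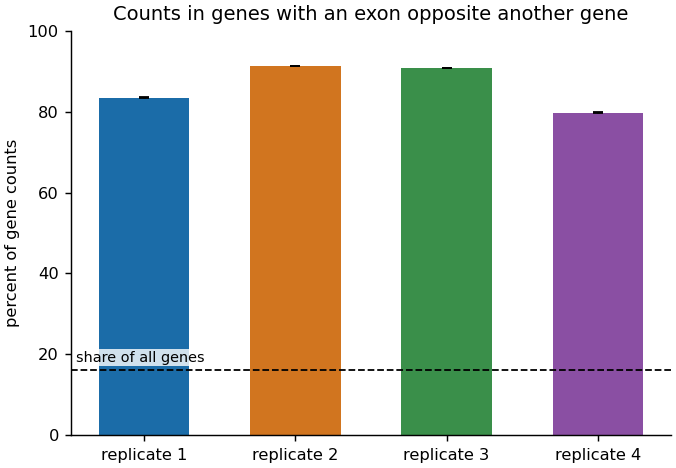
Percent of the gene counts of each library (bars, with 95% Wilson intervals) that fell in genes with an exon opposite an exon of another gene. The dashed line is the share of such genes among all annotated genes, with or without a count, 16.2%, and the bars lie between 79.9% and 91.5%.

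On their own strand, the Th2 cytokine genes Il4, Il5 and Il13 had counts in every library, while Ifng and Il17a had almost none. Il4 (chromosome 11, 53602982 to 53618669) had 68.2 ± 3.31 TPM (SD, n = 4), Il13 (chromosome 11, 53631324 to 53634702) 97.8 ± 83.6 TPM and Il5 (chromosome 11, 53720794 to 53725106) 5.27 ± 5.73 TPM. Ifng, the Th1 cytokine gene, had 2 counts in replicate 1 and 0 in the others, and Il17a, the Th17 cytokine gene, had 0 in all 4. Own-strand counts were low for the T cell gene Cd3e too (19, 17, 22 and 32 in replicates 1 to 4). Counts near 0 therefore do not show that Ifng or Il17a RNA was absent. On the log2(TPM + 1) scale, which understates ratios to genes at 0, Il4 exceeded Ifng by 5.81 ± 0.55 and Il17a by 6.11 ± 0.07, Il13 exceeded Ifng by 5.92 ± 1.23 and Il5 exceeded Ifng by 1.91 ± 1.45. Each difference was positive in 4 of 4 libraries, with an exact two-sided sign-flip p = 0.13, which is the smallest that this test allows with 4 libraries. The sign-flip test therefore cannot reach 0.05, and the sizes and SDs describe these comparisons. Where the second gene has 0 counts, a difference cannot be negative. This holds for Il17a in all 4 libraries and for Ifng in all but replicate 1, so the sign there was fixed. The SD of the Il17a difference is that of Il4 alone. Without replicate 4, the Il5 difference was 1.26, and the mean of Il13 was 59.4 TPM and that of Il5 2.48 TPM. Il22, a further Th17 cytokine gene named after its values were seen, had 0, 2, 4 and 12 counts in replicates 1 to 4, against 6, 7, 1 and 17 for Il5.

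Among the transcription factors that set T-helper fate, Gata3, the Th2 regulator (chromosome 2, 9857078 to 9890034), had 12.2 ± 7.82 TPM on its own strand. It exceeded Tbx21, the Th1 regulator with 3.53 ± 4.66 TPM, by 1.86 ± 0.80 on the log2(TPM + 1) scale. The mean of Tbx21 was 1.24 TPM without replicate 4. Bcl6, the follicular helper regulator, had 3 counts in replicate 4 and 0 elsewhere, and Gata3 exceeded it by 3.37 ± 0.66. These differences were positive in 4 of 4 libraries (exact sign-flip p = 0.13 each), but where Bcl6 had 0 counts its difference could not be negative. Foxp3, the regulatory T cell regulator, went the other way. It had 121 ± 17.3 TPM and the Gata3 difference was -3.40 ± 0.77, negative in 4 of 4 libraries (exact sign-flip p = 0.13). Foxp3 shares 590 bp of exon with Ccdc22 on the other strand, so its counts cannot be assigned to it alone. Cd4 had 25.5 ± 19.8 TPM while Cd8a had 0 counts in all 4 libraries, a difference of 4.34 ± 1.31 (exact sign-flip p = 0.13). With Cd8a at 0 this difference could not be negative. Own-strand counts at or near 0 do not show that Bcl6 or Cd8a RNA was absent.

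**Figure D2:**
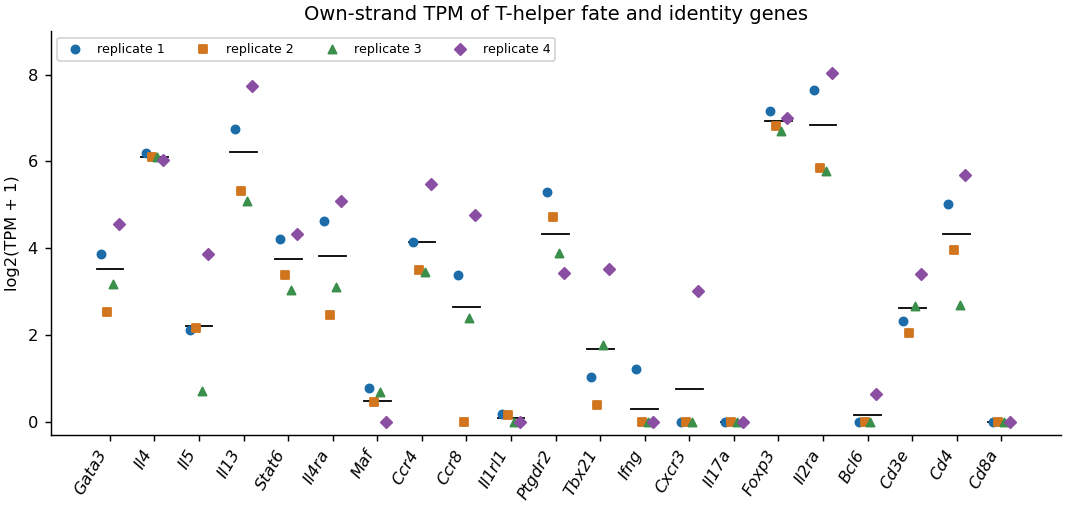
log2(TPM + 1) on the annotated strand of T-helper fate and T cell identity genes. Each symbol is 1 library and each line the mean of the 4 libraries. Il4 and Il13 lie well above Ifng and Il17a, while Foxp3, which has an exon opposite Ccdc22, lies above Gata3.

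Several fate genes have a noncoding gene annotated on the other strand within or across their exons, and there the counts were much higher. Gm13256 shares 155 of its 520 bp with Gata3 and had 643, 1094, 678 and 389 counts in replicates 1 to 4, while Gata3 had 63, 25, 32 and 73. Gm12214, all of whose 417 bp lie opposite Il5 (chromosome 11, 53723953 to 53724618), had 1092, 1961, 846 and 1001 counts against 6, 7, 1 and 17 for Il5. Gm44876 opposite Il4ra, a chain of the IL-4 receptor, had 1079 ± 155 CPM (SD, n = 4) against 67.8 ± 50.8 for Il4ra, and Gm15655 opposite Maf, a factor that acts on Il4, had 56.6 ± 23.6 CPM against 2.39 ± 1.76. The same held for Cd3e, a gene of the T cell receptor complex outside the fate lists, with 842 ± 133 CPM in Gm48719 on the other strand. The highest was Gm16008, which shares 414 of its 1324 bp with Tnfrsf18, the gene of the costimulatory receptor GITR, at 8318 ± 1220 CPM. Over all lists, 31 genes had such a noncoding gene that shared at least 100 bp and itself had at least 20 counts over the libraries. In 30 of these pairs it had more counts per kb than the list gene. Il21 was the exception, with 1523 ± 171 CPM against 111 ± 18.7 CPM for Gm12534. The minimum was set on the noncoding gene alone, and list genes without a count were kept, so the selection favoured this outcome. Pairs such as Cd22 and Gm29439, where the noncoding gene had no count, were left out. The 30 of 31 therefore does not show how often such noncoding genes are the denser. The pairs described here were chosen after their values were seen.

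**Figure D3:**
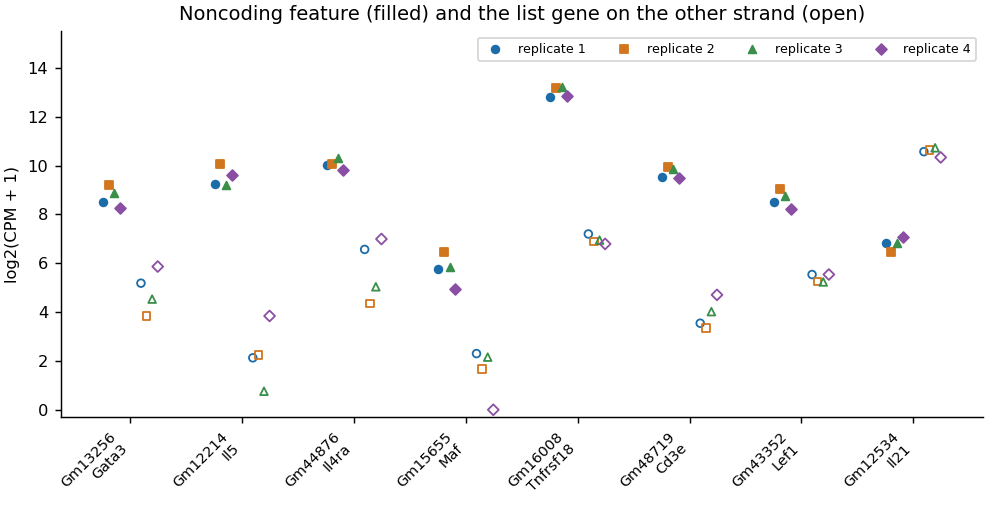
log2(CPM + 1) per library of noncoding genes (filled symbols, upper name) and of the list gene on the other strand with which each shares exon sequence (open symbols, lower name). The noncoding gene lies higher in each pair except Gm12534 and Il21.

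As groups, with all members included, the Th2 list stood above the Th1, Th17 and follicular helper lists and not above the regulatory T cell list. The Th2 list had a median of 8.78 ± 6.00 TPM (SD over 4 libraries), above 99.1% of 10000 random lists of detected genes, with 15 of 20 members at a mean TPM of at least 1. The Th1 list had 2.01 ± 1.79 TPM, above 39.2% of random lists, led by Il12rb2 with 14.7 ± 7.52 TPM, which shares 1519 bp of exon with Serbp1. The Th17 list had 0.585 ± 0.225 TPM, above 2.68% of random lists, although Batf had 87.5 ± 38.0 TPM. Only 8 of the 12 Th17 members had a count, while random lists held only genes with a count. This favoured a low percentile for the Th17 list. The regulatory T cell list had 10.1 ± 1.09 TPM, with Il2ra, the high-affinity IL-2 receptor chain, at 144 ± 105 TPM and Ctla4 at 89.1 ± 77.0 TPM. The follicular helper list had 2.34 ± 1.25 TPM, with Il21 at 428 ± 32.2 TPM. On the log2(TPM + 1) scale the Th2 median exceeded the Th1 median by 1.67 ± 0.69, the Th17 median by 2.45 ± 1.03 and the follicular helper median by 1.44 ± 0.41, each in 4 of 4 libraries (exact sign-flip p = 0.13). It differed from the regulatory T cell median by -0.41 ± 0.90, above 0 in 2 of 4 libraries (exact sign-flip p = 0.50). With only members of a mean TPM of at least 1, the difference to the Th17 list was 0.57 ± 0.66 (exact sign-flip p = 0.25) and was no longer positive in 4 of 4 libraries. The difference to the regulatory T cell list was then -1.21 ± 0.83. Leaving out replicate 2, 3 or 4 gave -0.10, -0.22 or -0.73 for the regulatory T cell list, and without replicate 4 the Th1 median was 1.18 TPM and the mean of Ctla4 52.8 TPM.

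Within the Th2 list, the own-strand values of the receptors and regulators covered a wide range, which was not taken as a range of mRNA levels. Il24 had 21.05 ± 10.5 TPM, Ptgdr2, the prostaglandin D2 receptor gene CRTH2, 21.8 ± 12.7 TPM, Ccr4 20.2 ± 16.1 TPM, Il4ra 17.3 ± 13.5 TPM, Stat6 13.4 ± 5.88 TPM and Ccr8 9.98 ± 11.5 TPM. Without replicate 4, Ccr4 had 12.3 and Ccr8 4.56 TPM. Il1rl1, the gene of the IL-33 receptor, had 1 count in each of replicates 1 and 2 and 0 in the others, and Maf had 0.424 ± 0.319 TPM. Ptgdr2 shares 1031 of its 2644 bp with Ccdc86 on the other strand. Among Th1 genes, Cxcr3 had 10 counts in replicate 4 and 0 in the others.

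T cell identity, activation, cytokine, growth and metabolic lists all had counts. The T cell receptor and signalling list had a median of 20.5 ± 19.7 TPM, above 99.97% of random lists, with Cd2 at 63.1 ± 50.4 and Cd5 at 36.8 ± 26.8 TPM. Cd247 had 79.6 ± 5.57 TPM but shares 3007 of its 5329 bp with Pou2f1 on the other strand. The activation list had 11.8 ± 14.0 TPM, with Irf4 at 157 ± 27.0 and Tnfrsf4, the OX40 gene, at 72.8 ± 53.4 TPM. The further cytokines had 14.9 ± 13.3 TPM, and there Lta had 54.7 ± 43.2, Il9 46.6 ± 56.1 and Il10 33.8 ± 7.26 TPM. The inhibitory receptor list had 4.11 ± 2.62 TPM, with Btla at 56.2 ± 24.8 TPM, and the naive T cell list 4.55 ± 3.52 TPM, with Ccr7 at 18.3 ± 12.5 TPM. The proliferation list had 9.96 ± 7.94 TPM with all 21 members at a mean TPM of at least 1. Mki67 had 29.8 ± 22.1 TPM. Glycolysis was the highest of the metabolic lists at 45.9 ± 35.9 TPM, with Ldha at 130 ± 91.9 TPM, against 8.03 ± 6.75 TPM for cholesterol synthesis, 3.13 ± 2.27 TPM for stress genes and 1.61 ± 1.99 TPM for interferon-stimulated genes. Replicate 4 held the highest value of several of these lists. Without it the medians were 11.6 TPM for T cell identity, 4.91 for activation, 8.31 for the further cytokines, 4.93 for cholesterol synthesis and 0.701 for interferon-stimulated genes, and the means of Lta and Il9 were 34.6 and 20.003 TPM.

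Most markers of other cell types were at or near 0 on their own strand. Own-strand counts were low for the T cell gene Cd3e as well (19, 17, 22 and 32 in replicates 1 to 4), so values near 0 do not show that other cell types were absent. The median of the CD8 and natural killer, B cell, myeloid, granulocyte, red cell and platelet, and stromal lists was 0 TPM in all 4 libraries. In the granulocyte list Epx had 4 counts in replicate 2, and the other 10 members had none in any library. Some members did have counts, among them 8 of the 13 B cell genes, such as Cd22 (14, 15, 12 and 1 in replicates 1 to 4). The red cell gene Alas2, which has an exon opposite Apex2, had 8.60 ± 3.01 TPM. Csf1r, a macrophage receptor gene, had 131 ± 5.35 TPM but shares 871 bp of exon with Hmgxb3 on the other strand. Cd79a, a B cell receptor component, had 35, 41, 9 and 2 counts in replicates 1 to 4, Cd68 had 16, 11, 33 and 0, and Pecam1, expressed by endothelium and by some leukocytes, had 15.7 ± 5.29 TPM. Of the 56 members of the B cell, myeloid, granulocyte, red cell and platelet, and stromal lists with no exon opposite another gene, 16 had any count, and all 56 together had 170, 167, 177 and 133 counts.

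Replication-dependent histones and the structured noncoding RNAs of the fixed list, which carry no poly(A) tail, were at or near 0 on their own strand. None of the 16 measured structured noncoding RNAs, such as Rn7sk and Rmrp, had a count. The replication-dependent histones had a median of 0 TPM, with counts for 9 of 22 genes, while the polyadenylated histone variants had 13.9 ± 7.23 TPM, H1f0 among them at 34.4 ± 12.8 TPM. H3f3a, another of these variants, had 1.74 ± 1.21 TPM. Own-strand values near 0 therefore do not show whether poly(A) RNA was selected. The mitochondrial mRNAs had a median of 653 ± 354 TPM and the mitochondrial rRNAs 199 ± 160 TPM. The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l had 0 counts in all 4 libraries. Nnt, a mitochondrial proton pump gene that is truncated in the related strain C57BL/6J, had 8, 0, 11 and 7 counts. The highest TPM values belonged to mt-Nd6 at 40495 ± 6672, Gm20412 opposite Tgm2 at 29258 ± 2981 and CT010467.1 at 24732 ± 6121. They were followed by Gm45552, Gm20721, the tRNA gene mt-Tp and 4 short genes opposite Serf2, Cish, Bnip3 and H2afj, down to 9511 ± 1714 TPM for Gm44364.

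T cell, growth, glycolysis and activation genes were higher in replicates 1 and 4 than in replicates 2 and 3, and for several of these lists the deviations lay at the edge of random lists matched on mean expression. The T cell list deviated from the 4-library mean by 0.71, -0.61, -1.42 and 1.32 (mean log2 CPM, replicates 1 to 4), the last above all 10000 random lists and the one before it below all of them. Proliferation genes deviated by 0.57, -0.64, -1.08 and 1.15, and glycolysis genes by 0.79, -0.82, -0.94 and 0.97. Activation genes deviated by 0.54, -0.69, -1.13 and 1.29, stress genes by 0.23, -0.43, -0.83 and 1.02 and cholesterol synthesis genes by 0.42, -0.66, -0.91 and 1.16. Ribosomal protein genes, with 1.92%, 0.673%, 0.706% and 1.95% of the counts, and the mitochondrial rRNAs, with medians of 278, 54.2, 79.2 and 387 TPM, were likewise higher in replicates 1 and 4. The Th2 list deviated by 0.51, -0.42, -0.62 and 0.53, at percentiles 93.4, 22.7, 11.4 and 67.5. TMM scaling moved the libraries by 0.12, -0.24, -0.13 and 0.25 against total counts, less than each of these deviations. The share of counts in genes with no exon opposite another gene was also higher in replicates 1 and 4, at 16.4%, 8.54%, 9.14% and 20.1% in replicates 1 to 4. Restricted to such genes and compared with random lists of such genes, the T cell list kept percentiles of 99.8 and 100 in replicates 1 and 4 and 0 in replicate 3, but lay at 44.5 in replicate 2. In replicates 1 to 4 proliferation genes then lay at 95.6, 13.4, 0.05 and 99.9, glycolysis genes at 99.8, 2.23, 0.70 and 98.4, activation genes at 64.5, 20.2, 2.42 and 99.2, stress genes at 54.5, 2.15, 1.04 and 99.95 and cholesterol synthesis genes at 44.5, 59.3, 2.36 and 98.0.

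Over 7752 genes with a mean count of at least 10, 6838 varied beyond Poisson sampling (chi-square test, Benjamini-Hochberg 0.05), and the biological coefficient of variation was 0.575. Separate biological samples vary beyond counting noise as a rule, so the count describes these libraries and is not a difference between conditions. In no pair were the counts alike within sampling noise, as those of a library deposited more than once would be, and the Pearson correlation of log2 CPM across genes ranged from 0.745 for replicates 3 and 4 to 0.914 for replicates 2 and 3. Comparing 1 library with the other 3 describes libraries, not conditions. In edgeR's quasi-likelihood test at an adjusted threshold of 0.05, replicate 2 stood apart in 1 gene, Fgfbp3, a growth factor carrier (0, 119, 0 and 1 counts, adjusted p = 0.000665). In replicate 3, 3 genes passed in edgeR, all lower, where DESeq2 called 0. These were Tsix (adjusted p = 9.18e-17) and Gm27520 within Xist (adjusted p = 5.27e-10), both at 0 counts in replicate 4 as well and so not particular to replicate 3, and Themis, a thymocyte selection gene (93, 26, 0 and 170 counts, adjusted p = 0.00249). Replicates 1 and 4 stood apart in 0 genes in edgeR, with 33 and 683 genes at an unadjusted p under 0.05, and DESeq2 called 0, 1, 0 and 0 genes in replicates 1 to 4. The counts depended on which libraries were compared. By chi-square per gene, replicates 1 and 4 (10.4) and replicates 2 and 3 (7.56) were the closest pairs, against 20.4 to 41.1 otherwise. By Pearson correlation, replicates 1 and 2 (0.875) lay nearer than replicates 1 and 4 (0.860). The highest counts below came where the closest partner was left out. A split of 2 libraries against 2 enters the spread in a test of 1 against 3. Few calls there do not show that the replicates were alike. The tests that leave out 1 library set a single library against 2, so their counts are not read as genes that differ in that library. Without replicate 1 replicate 4 stood apart in 1083 genes, and without replicate 4 replicate 1 stood apart in 169. Without replicate 2 replicate 3 stood apart in 741 genes, and without replicate 3 replicate 2 stood apart in 400. Without replicate 2, replicate 1 stood apart in 2 genes and replicate 4 in 3, and without replicate 3 replicate 4 stood apart in 4. Without replicate 1, replicate 2 stood apart in 2 genes. Among genes with a mean TPM of at least 10, the widest spread besides Tsix, Gm27520 and Fgfbp3 was in Emc2 (48, 0, 0 and 47 counts), Psmd14 (82, 21, 0 and 69), Chchd2, Snhg1, Cd40lg (13, 1, 1 and 62), Itm2a and Il9 (27, 12, 0 and 55).

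Genes of the sex chromosomes separated the libraries. Tsix, annotated opposite the X-inactivation RNA gene Xist (chromosome X, 103431517 to 103484957), had 4108 counts in replicate 1, 5430 in replicate 2, 2 in replicate 3 and 0 in replicate 4. Xist itself had 407, 130, 20 and 0. The Tsix values are counts on its annotated strand and were not taken as a level of Tsix RNA. The genes of chromosome Y had 0 counts in replicates 1 and 2, 31 in replicate 3 and 124 in replicate 4. Eif2s3y had 0, 0, 12 and 75 counts, Uty 0, 0, 17 and 24, and Ddx3y 0, 0, 2 and 18. A count of 0 allows up to 1.68 CPM in replicate 1 and 1.62 CPM in replicate 2. The sex-linked list had a median of 1.03 ± 1.43 TPM, and 0.369 TPM without replicate 4. The labels record no sex and give the 4 libraries the same donor entry.

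**Figure D4:**
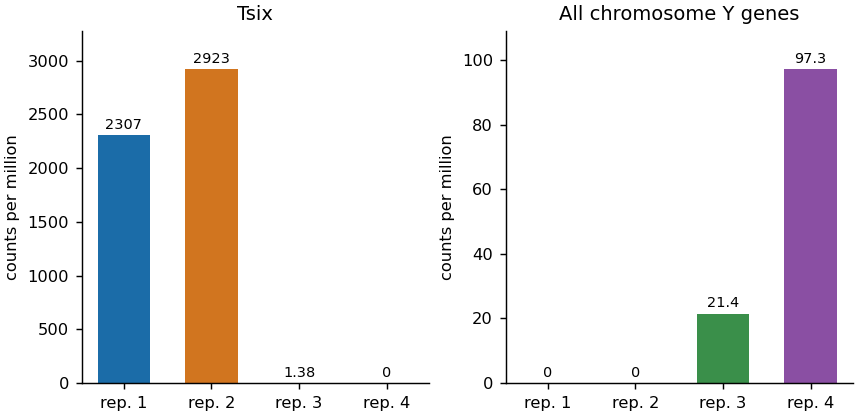
CPM of Tsix (left) and of all chromosome Y genes together (right) in each library. Tsix stands at 2307 and 2923 CPM in replicates 1 and 2, and chromosome Y at 21.4 and 97.3 CPM in replicates 3 and 4.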

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

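Of 58 results examined for a library far from the other 3, 6 stood out. The rule used picks about 1 group in 20 by chance for continuous values, which does not hold here: Bcl6, Cxcr3 and Ifng were at 0 in the other 3 libraries, where any count stands out, and the Il4 over Ifng ratio rests on the same 2 Ifng counts. The tests on the strand of the counts and on the sex-linked genes were chosen after the pattern was seen, and the median density in the second pattern was chosen after the test set beforehand had given its value.

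Replicate 1 lay lowest in the Il4 over Ifng ratio, at 4.98 against 6.03 to 6.11, and was the library with TPM above 0 for Ifng, at 1.32 from 2 counts. Replicate 4 lay highest in the Il13 over Ifng ratio, at 7.74 against 5.09 to 5.53. Replicate 4 was also the library with TPM above 0 for Cxcr3 (7.13) and Bcl6 (0.552, from 3 counts), and it was highest for Ddx3y, at 4.27 against 0 to 0.382.

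The first pattern is the concentration of counts in genes opposite other genes. A candidate explanation is that fragments were assigned to the strand opposite the RNA, as when a stranded library is counted with the other strand setting; the headers call the alignments stranded and give strand option 1, and the kit is not named. In 302 features nested in exons of a protein-coding gene, the host had a median of 0.00756 of the feature's counts per kb, and 84.8% (95% Wilson interval 80.3 to 88.4; a share of 0.848) of the features were denser than the host, short of the bound of 0.9 first set for that share, with 29 of the 46 remaining hosts having further exons opposite other genes. The ratio of 0.00756 argues against a library that does not mark strand, which would give both strands like densities. Antisense transcription of the nuclear genome cannot account for mt-Nd6, a mitochondrial gene. In every library mt-Nd6 had at least 87.3 times the median density of the 12 mRNAs of the other mitochondrial strand. That median is lowered by genes without a count, such as mt-Co2 and mt-Co3. The densest of the 12 had at most 2853 counts per kb in any library, and mt-Nd6 at least 38990. For the nuclear genes, which hold nearly all of the counts, antisense transcription had no test of its own. To give the values above, antisense RNA would have to exceed host mRNA per kb in most of the 302 pairs. The median host would then have 0.00756 of the density of the antisense RNA. Only in that form does antisense transcription of the nuclear genes stay open.

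The second pattern is the higher share of counts in genes with no opposite exon in replicates 1 and 4 (16.4% and 20.1%, against 8.54% and 9.14%), which goes with their higher T cell, growth and glycolysis counts. Genomic DNA would raise markers of other cell types alike. Of the 56 such markers, 16 had any count, and Pecam1 held 95, 79, 120 and 106 of their 170, 167, 177 and 133 counts in replicates 1 to 4. Together the 56 gained -0.0344 of what the mean gain per kb requires, a value that rests mostly on few genes. A few dominant genes do not account for the higher share of counts either. The quotient of the lowest share of replicates 1 and 4 over the highest of replicates 2 and 3 was 1.76 without the 10 genes of highest count and 1.80 with them. Whether more fragments kept the strand of the RNA in these libraries stays open: the test set beforehand, the same quotient for summed host against nested feature counts, gave 1.11, between the bound of 1.1 against and of 1.3 for this explanation. The quotient of the median densities was 2.57, but this measure was picked once the first value was known and decides nothing.

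The third pattern is Tsix against the Y-linked genes. Cells of female animals in replicates 1 and 2 and of male animals in replicates 3 and 4 are a candidate explanation: in 4 of 4 libraries Tsix counts above 3 and counts on chromosome Y excluded each other. For Tsix, this explanation takes its counts as Xist RNA assigned to the other strand. It thus depends on the candidate explanation of the first pattern, which was not shown for this gene. The pattern does not follow the share of genes with no opposite exon, which groups the libraries otherwise, and Tsix CPM in replicates 1 and 2 was at least 980 times the higher of the limits that 3 counts set in replicates 3 and 4. Xist had 20 counts in replicate 3, and the sex of the animals is not recorded, so this stays a hypothesis.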

How the results depend on the processing

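The restrictions to genes with or without an opposite exon were chosen after the data were seen. All 13 within-library ratios and list differences kept their direction in all 86 alternatives, but for most alternatives this was fixed in advance. A difference of the same sign in 4 of 4 libraries keeps it when 1 library is left out. Another pseudocount or FPKM cannot change the sign of a gene ratio within a library. None could pass 0.05 in the sign-flip test with 4 libraries, so the alternatives say nothing of their side of the threshold. With a pseudocount of 0.1 the ratios to genes near 0 grew, as for Il4 over Il17a (9.41 against 6.11). No list level moved by more than its SD, but leaving out 1 of 4 libraries cannot move a mean that far. Only rescaling, tried on 23 lists, could have done so. Without replicate 4, the level of the activation list fell from 11.8 to 4.91 TPM. The common coefficient of variation ranged from 0.430 to 0.769. Genes detected fell to 3667 at a TPM of at least 5 and to 2710 among genes without an opposite exon. Genes beyond sampling noise numbered 11679 without a filter on low counts, 3379 among genes without and 3459 among genes with an opposite exon, because more or fewer genes were tested. Leaving out 1 library gave 0 to 169 genes standing apart in replicate 1, 1 to 400 in replicate 2, 2 to 741 in replicate 3 and 3 to 1083 in replicate 4. With median-of-ratios factors, and likewise with no filter, replicate 2 stood apart in 3 genes and replicate 4 in 3. The DESeq2 test gave 0 in replicate 3. Among genes with an opposite exon replicates 2 and 3 stood apart in 0, and among those without replicate 3 in 0. The highest numbers came where the closest partner by chi-square per gene (1 with 4, 2 with 3) was left out. The cause of this pairing and of the other changes was not tested. Posterior mean and credibility-interval alternatives were not run, because the values used are counts. Of 143 named genes, 52 had a mean TPM that leaving out 1 library moved by over 1.5 times, in 34 of them replicate 4. Genes under about 3 counts, such as Ifng, Bcl6 and Il1rl1, are at the limit of detection, and depth and strand assignment were not separated as reasons.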

Other observations

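The genes to describe here were picked after their values were seen, and no test was added for them. Il21, the gene of a cytokine of helper T cells, had the highest own-strand level of the cytokine genes examined, with 2704, 2953, 2450 and 1645 counts in replicates 1 to 4. Of its 5259 bp of exon, 469 bp lie opposite Gm12534, which had 198, 163, 163 and 170 counts. Other list genes with a steady own-strand level across the libraries were Irf4 (852, 764, 895 and 617 counts) and Il10 (41, 50, 49 and 45), neither of which has an exon opposite another gene, and Ccna2 (700, 616, 510 and 554) and Ddit3 (379, 315, 290 and 178), which do. Il2ra (1334, 427, 311 and 1221), Ctla4 (242, 92, 93 and 374) and Hspa8 (789, 184, 219 and 580), also without an opposite exon, were higher in replicates 1 and 4, the libraries with the larger share of counts in such genes.

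Further noncoding genes opposite genes of T cell state had counts in every library. Gm43352 opposite Lef1, a factor of naive T cells, had 646, 964, 616 and 382 counts, Bach2os opposite Bach2 519, 753, 416 and 462, Gm11802 opposite Tox 88, 101, 90 and 61, Gm12868 opposite the glucose transporter gene Slc2a1 1019, 1547, 1000 and 737, and Gm26762 opposite the glycolysis gene Gpi1 8975, 12296, 9524 and 6098. These are the values of noncoding genes, and none was taken as a level of the gene it lies opposite.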
